A study of Homo sapiens with 4 samples.

How the data were processed

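ATAC-seq libraries were made from Kasumi-1 cells, 2 labelled sgNT and 2 labelled SETD8 knockout, with a one-step kit and paired-end sequencing per the labels' protocols. Groups were taken from the sample titles, and replicate 2 stands for the libraries numbered 2 there. The submitters' processing notes name cutadapt, Bowtie2, SAMtools, MACS2 2.1.2, deepTools and ChIPseeker and the build hg38, with no order or settings. How reads were shifted for the transposase cut, whether duplicates and mitochondrial reads were removed, and how libraries were scaled is not given in the sources used here.

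The authors deposited 2 tables of a treated against control comparison, with 1 row per peak. Per the file headers, the second table gives a mean log2 level, a log2 level for the knockout and the control library of replicate 2, the log2 fold change, its p-value and an adjusted p-value. The first deposited table has numbered columns in place of names, and its mean log2 level, log2 fold change, p-value and adjusted p-value were identified by their order and ranges. Its 2 further columns, in the place where the second table gives the level of each library, were not used, because the libraries they cover are not named. Which libraries entered the first table, and whether those of replicate 2 did, is not stated. The direction of its fold change, treated against control, was read from the name of the deposited table. It also carries the ChIPseeker annotation of each peak. The deposited log2 levels of the second table are of whole reads in the knockout library (100% of 2294 weak values checked, within 0.005 on the log2 scale), and of reads multiplied by 0.918 in the control library. This gave 2091370 and 5345010 reads in peaks. The tables were scaled separately, so fold changes and their medians were computed within a table. Exceptions are the replicate-block fit on the fold changes of both tables and the differences of peak level between tables, which the separate scaling can shift.

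Read counts for all 4 libraries were not used here, so the planned count test across the groups was not run, and the authors' adjusted p-values stand in its place. The planned exact tests of annotation classes and the adjusted p-values over gene lists were replaced by medians with intervals and by percentiles, because peaks and genes are not replicates and the second table has 1 library per group. Motif analysis was not run, because it needs a genome sequence. Promoter means the class that the annotation names so, within 3 kb of a start site. Peaks of the second table have no annotation. Each took the annotation and gene of the first-table peak it overlapped most, by at least 1 bp, and 11117 peaks joined in pairs while 2460 stayed without annotation. Gene identifiers were matched to current symbols of assembly GRCh38.p14. The nearest gene of a distal peak need not be its target.

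Medians carry 95% intervals from 1000 bootstrap draws over peaks. These describe the peaks of the libraries at hand, not new cultures. The level trend was removed by subtracting the median of 20 bins of equal size by mean level, and the regional trend by subtracting the median of the other peaks of the same 5 Mb bin with at least 10 peaks. Segments were runs of at least 5 bins whose level-adjusted medians in the second table were all beyond 0.1 in size with the same sign. For the gene lists, fixed with the named-gene rule before the data were examined, each gene's strongest promoter peak was used and its list median was placed among 10000 random lists drawn from 10 bins of peak level. The share of a list's genes with any peak lower by at least 1 was placed among lists matched on the number of peaks per gene. Lists needed at least 3 genes. The rule named all KMT5A peaks, and per table the 8 other and 5 promoter peaks with the largest increase and decrease, 1 per gene and with a mean level at or above the median, and up to 4 members per list. It asked for peaks past an adjusted p of 0.05. As none passed, its fallback by size was used. Some genes that the rule named are not reported here. Percentages of peaks cover these peaks only.

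Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for a replicate-block alternative on the 2 fold changes of each joined peak. Tested on simulated data for the 11117 joined peaks, that fit recovered 100 of 100 peaks with a log2 change of 2 and 100 of 100 with 3, and called 10 unchanged peaks. The simulated noise had the same size at all peaks (standard deviation 0.325), and smaller changes were not simulated. Recovery and false calls at smaller changes, or with noise that varies with level, are therefore not known from it. For the first-table promoters, 47 of 50 simulated unchanged lists of 20 genes stayed inside the central 95%, and 37 of 50 lists shifted by 0.3 and 50 of 50 shifted by 0.5 were found. Alternatives covered the fold size, the adjusted p threshold, a level filter, centring, promoter width, autosomes, overlap, the peaks counted per gene, and the trend and scaling adjustments added later.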

Results

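Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and leaves sequencing adapters, in Kasumi-1, an acute myeloid leukaemia cell line that carries the t(8;21) translocation joining RUNX1 to RUNX1T1. The knocked-out gene was SETD8, now named KMT5A, the enzyme that monomethylates histone H4 at the residue known as H4K20. The series title places the experiment in a study of enhancers, leukaemia stem cells and mitochondria. The 4 libraries fell into 2 groups, SETD8 knockout and sgNT control, with 2 libraries each. The values came from 2 deposited tables of peaks in hg38. The first table held 20556 peaks of median width 602 bp and named no library. The second held 13577 peaks of median width 847 bp and compared the knockout and control libraries of replicate 2. The knockout library of the second table had 2091370 reads in peaks and its control library 5345010. The median peak of that table had 125 knockout and 323 control reads, a depth at which counting error alone spans 0.298 on the log2 scale on either side. In the first table the median peak had a mean level of 142 normalised reads per library, and the depth of its single libraries was not analysed here. Each comparison within the second table rested on 1 library per group, so its differences have no replicate check.

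KMT5A itself spans positions 123384132 to 123409353 of chromosome 12. Its promoter was open in both tables and had a lower level in the knockout. In the authors' first deposited table the promoter peak at 123383664 to 123384357 had a log2 fold change of -0.82 with an adjusted p of 0.731, which lay 0.05 above the median of all peaks of that table. In the authors' second deposited table the promoter peak at 123383687 to 123384415 had a fold change of -1.45 with an adjusted p of 0.578, or -0.22 relative to the median. That peak held 251 reads in the knockout library and 685 normalised reads in the control. A peak further into the gene, at 123388468 to 123389052, had a fold change of -1.54 in the authors' second deposited table, from 95.01 knockout reads and 276 normalised control reads. A guide that edits coding sequence need not alter accessibility, so these peaks check the sample labels only in part.

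Normalised levels were lower at nearly all peaks in the knockout libraries, and the gene lists followed this shared shift. All 17 gene lists fixed in advance had a negative median promoter fold change in the first table, from -1.31 for erythroid and megakaryocyte markers to -0.61 for lymphoid markers. All 15 lists with at least 3 genes in the second table did so too, from -1.55 for erythroid and megakaryocyte markers to -0.98 for the LSC17 genes, a leukaemia stem cell expression score. Over all peaks the median log2 fold change was -0.87 in the first table (quartiles -1.17 and -0.53) and -1.23 in the second (quartiles -1.43 and -1.01). Of the first table, 18979 peaks (92.3%) were lower and 1532 higher, and 7998 were lower by at least 1 against 105 higher by at least 1. Of the second, 13393 peaks (98.6%) were lower and 182 higher, with 10335 lower by at least 1 and 18 higher by at least 1. This split depended on the scaling between libraries. When the second table was rescaled to the reads in peaks of each library, 6657 peaks were lower and 6920 higher, with 28 lower and 277 higher by at least 1. The ratio of normalised reads in peaks used for this, 0.426, equals the median fold change on the linear scale. The rescaling was thus the same as centring, and a near-even split was built in. When the first table was centred on its median, 408 peaks were lower and 1134 higher by at least 1.

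No single peak passed the authors' test in either table. The second table has 1 library per group, so its test had no replicates from which to estimate spread. The smallest adjusted p was 0.731 in the authors' first deposited table and 0.578 in the authors' second deposited table. At an unadjusted p under 0.05 there were 329 peaks in the first, 309 lower and 20 higher, where chance alone gives 1028. The second had 19 such peaks, 17 lower and 2 higher, where chance gives 679. Both counts lie below those of chance, so these p-values are not calibrated. The lack of passing peaks therefore does not show that peaks were unchanged. Because the shift was shared by nearly all peaks, gene values below are as deposited unless said otherwise, and one above its table's median of -0.87 or -1.23 was lowered less than most peaks. The labels do not say whether the libraries numbered 2 came from separate cultures or from another guide, so the spread between replicates may be technical.

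Peaks were ranked by fold change among those at or above the median level of their table, 1 per gene with an admitted symbol, and weaker peaks beyond these values are left out of the rankings. Among the ranked peaks of the first table, the lowest promoter was that of DPYSL3, a cytoskeleton-associated gene of the LSC17 score. Its peak on chromosome 5 at 147403870 to 147404707 had a fold change of -3.13 in the authors' first deposited table, with p = 0.00662 and an adjusted p of 0.731. The promoters of POU3F3, a neural transcription factor, and of BLMH, which encodes bleomycin hydrolase, stood at -2.73 and -2.50 in the same authors' deposited table, with GRASLND at -2.55 and ATXN2L at -2.43. Away from promoters, the lowest ranked site was an intron of EPAS1, the gene of the hypoxia-inducible factor HIF-2alpha, on chromosome 2 at 46315149 to 46315729, with -2.90 in the authors' first deposited table. Intronic peaks of LPP (-2.54), NIBAN2 (-2.47), ANGPT4 (-2.38) and DENND1A (-2.33) and intergenic peaks nearest PPP1R21 (-2.46), ME3 (-2.45) and BOLA3 (-2.39) completed this set in the authors' first deposited table. Of the 6 of these 13 peaks that joined a peak of the second table, only that of BLMH lay below the median there, at -0.17 relative to it. The peaks at EPAS1, NIBAN2, PPP1R21, BOLA3, DENND1A, GRASLND and BLMH, 7 of the 13, lie in the lowered chromosome segments described below, which hold 10.2% of the ranked peaks, so these values include the regional shift.

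The highest of the ranked peaks in the first table were a distal peak nearest PROS1, at 2.73 in the authors' first deposited table (chromosome 3, 93470358 to 93470787), and one nearest EMBP1, at 2.36 (chromosome 1, 125180043 to 125180441). They lie 415626 and 3660698 bp from the start sites of these genes, so the gene names only locate them. Their mean levels were 6039 and 455 normalised reads, against 142 at the median peak of that table. Neither joined a peak of the second table, and how uniquely reads map at these sites was not analysed here. A distal peak near EGR1, an immediate early transcription factor, at -5849 bp from its start site, followed at 0.72 in the authors' first deposited table. Ranked peaks at TBC1D16 (0.49), AP3D1 (0.38), RALGDS (0.31), KAT6B (0.13) and DAP (0.08) were the others away from promoters in the authors' first deposited table. Among the ranked promoters the highest were those of GATM, which acts in creatine synthesis, at 0.62, SNX9 at 0.43, DOHH at 0.39, SDHB, a subunit of respiratory complex II, at 0.38, and RPL8, a ribosomal protein gene, at 0.34 in the authors' first deposited table. SNX9, DOHH and RPL8 were also above the median of the second table, by 0.77, 0.34 and 0.45, whereas GATM and SDHB were below it, at -0.23 and -0.35 relative to it. RPL8 lies in the raised segment of chromosome 8, whereas TBC1D16 and RALGDS lie in lowered segments, against the direction of their peaks.

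Among the ranked peaks of the second table, with the same level filter, the promoters lowest in the knockout were those of CUEDC1 (-2.36), WDCP (-2.35) and HLA-DMA (-2.32), which acts in peptide loading of MHC class II, in the authors' second deposited table. PHF19, an accessory subunit gene of Polycomb repressive complex, and GRN, which encodes progranulin, stood at -2.22 and -2.19 in the authors' second deposited table. The lowest ranked sites away from promoters were an intronic peak nearest CDC42EP3 (-2.33), one in an intron of VMP1 (-2.30), an autophagy gene, and one near DNAH17 (-2.22) in the authors' second deposited table. Peaks at RPTOR (-2.16), ARHGAP25 (-2.13), AKNA (-2.10), LPO (-2.03) and FAM174B (-2.03) followed in the authors' second deposited table. All of these 13 but HLA-DMA and FAM174B, 11 in number, lie in the lowered segments, which hold 11.3% of the ranked peaks, so most of these values include the regional shift as well. At the other end of this ranking, EEF1A1, the gene of a translation elongation factor, had a promoter peak on chromosome 6 at 73519982 to 73521297 with a fold change of 0.07 in the authors' second deposited table. The promoters of SLC16A9 (-0.11), TSNARE1 (-0.16), DLG5 (-0.23) and CFAP298-TCP10L (-0.34) came next among the ranked promoters in the authors' second deposited table. The least lowered ranked sites away from promoters were at DAP (-0.40), ASAP1 (-0.41), CELSR3 (-0.43), PSAP (-0.43), GPT2 (-0.56), THAP4 (-0.57), FRMD8 (-0.70) and FAM167A (-0.73) in the authors' second deposited table, and TSNARE1 and ASAP1 lie in the raised segment. Of the 26 peaks named from the first table, 12 joined a peak of the second and 5 lay on the same side of the median there. Of the 26 named from the second, all joined and 14 lay on the same side in the first. The names rest on size alone, since no peak passed the authors' test. A replicate-block fit on the joined peaks, described below, called 10542 as deposited and 18 once centred. That fit takes the 2 tables as independent, which could not be checked, and it was not used to name peaks.

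Enhancers are the chromatin that the series title names, so promoters were set against all other sites. Promoter peaks made up 57.3% of the first table and 80.9% of the annotated peaks of the second. As deposited, the median fold change of the first table was -0.92 at promoters, -0.76 in introns and -0.76 at distal intergenic sites. The difference of promoter minus other peaks was -0.16 (95% bootstrap interval over peaks -0.17 to -0.13). In the second table promoters stood at -1.26, introns at -1.31 and distal intergenic sites at -1.27, a difference of 0.03 (0.01 to 0.055). Promoter peaks are stronger, and the shift depended on peak strength. The lowest decile of peaks by level had a median of -0.20 and the highest -0.94 in the first table, against -0.89 and -1.28 in the second. Within deciles, other peaks were lower than promoters in 9 of 10 in both tables. With the level trend removed, a step chosen after the data were seen, promoters exceeded other peaks by 0.035 (0.02 to 0.055) in the first table and by 0.09 (0.07 to 0.11) in the second. The sign of the difference in the first table therefore turned with the adjustment.

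**Figure D1:**
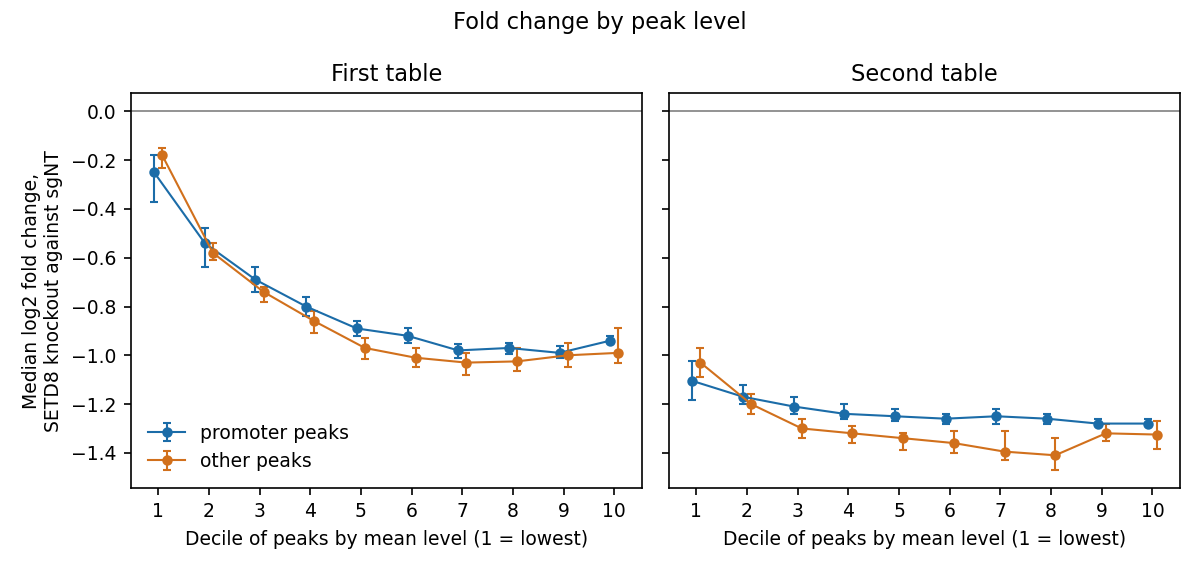
Median log2 fold change (vertical axis) of promoter peaks (blue) and other peaks (orange) in deciles of peaks ordered by mean level (horizontal axis), for each table; bars are 95% bootstrap intervals over peaks. All medians lie below 0, and other peaks lie below promoter peaks in 9 of 10 deciles in each table.

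Promoters of the LSC17 score genes had a median fold change of -0.75 in the first table, over 11 genes, and of -0.98 in the second, over 7 genes. These medians lay at percentiles 86.6 and 96.6 of 10000 random lists matched on peak level, inside the central 95%. With the level trend removed the second-table percentile was 97.6, outside that range, and 94.5, inside it, with that by chromosome region removed too. Of those genes, 28.6% had a promoter peak lower by at least 1, at percentile 0.095 of lists matched on peaks per gene, also outside the central 95%. In the authors' deposited tables the CD34 promoter, which marks blood progenitors, had fold changes of -0.64 and -0.60, and that of KIT, a stem cell factor receptor, had -0.61 and -0.89. These 2 promoters were picked after their values were seen, as were that of MYC, at -1.06 and -1.13, and the strongest RUNX1 promoter peak of each table, at -1.20 and -0.74, in the authors' deposited tables. The RUNX1 peaks of the 2 tables do not overlap, so their values are of different sites. Haematopoietic stem and progenitor regulators had medians of -0.80 (percentile 78.8) and -1.14 (percentile 89.5), and percentiles of 94.8 and 48.2 with the trends by level and by chromosome region removed. Of the 22 genes of that list with a peak in the first table, 11 had one lower by at least 1 and 2 had one higher by at least 1. The higher ones were weak distal peaks nearest GATA2, a progenitor transcription factor, at 1.16, and KIT, at 1.11, in the authors' first deposited table. An intronic RUNX1 peak on chromosome 21 at 34807469 to 34808726 stood at -1.65 and an IKZF1 intron at -1.62 in the authors' first deposited table.

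Genes of myeloid differentiation had a median of -1.05 in the first table (percentile 11.9) and -1.03 in the second (percentile 93.9), both inside the random range. The promoters of SPI1, CEBPD and CEBPA, transcription factors of the myeloid lineage, had -1.41, -1.25 and -1.20 in the authors' first deposited table and -0.97, -0.88 and -0.81 in the authors' second deposited table, where they were 0.26, 0.35 and 0.42 above the median and so lowered less than most. Genes associated with t(8;21) had medians of -1.04 (percentile 21.6) and -1.14 (percentile 88.8). Among them the promoter of ROBO1, an axon guidance receptor, was low in both of the authors' deposited tables, at -1.81 and -1.92, as was that of JUP at -1.21 and -1.67. The PAX5 promoter, from a B cell transcription factor gene active in this leukaemia type, stood at -0.71 and -1.63 in the authors' deposited tables.

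Of the 5 mitochondrial lists, 2 were less lowered than the random range in the first table and 0 in the second. The 52 oxidative phosphorylation genes with a promoter peak there had a median of -0.785, at percentile 98.7 of random lists, and the 16 genes of mitochondrial apoptosis one of -0.725, at percentile 98.3. Their second-table medians were -1.22, at percentile 76.9, and -1.15, at percentile 90.2. With the trends by level and by chromosome region removed, the first-table percentiles were 62.4 and 87.8. Genes of mitochondrial biogenesis and genome maintenance stood at percentiles 97.1 and 44.2, those of dynamics and mitophagy at 92.8 and 50.3, and those of the mitochondrial and integrated stress responses at 55.0 and 96.7. The members named next were low in both tables, and ATP5PD, ATP5MC1, PHB1, MTHFD2 and PSAT1 lie in the shifted chromosome segments described below. The promoters of ATP5PD and ATP5MC1, subunits of ATP synthase, had -1.60 and -1.43 in the authors' first deposited table and -1.82 and -1.88 in the authors' second deposited table. MTHFD2, a mitochondrial folate enzyme, had -1.68 and -1.85, PSAT1, of serine synthesis, -1.45 and -1.57, and TFAM, which packages mitochondrial DNA, -1.12 and -1.58 in the authors' deposited tables. PHB1, a prohibitin, had -1.20 and -1.93, and MFN1, of mitochondrial fusion, -1.45 and -1.48 in the authors' deposited tables. Others stood above the first-table median, such as the promoters of ATP5F1A, of ATP synthase, at -0.29 and of COX6C, of cytochrome oxidase, which lies in the raised chromosome 8 segment, at 0.35 in the authors' first deposited table. All these members were picked after their values were seen. A weak distal peak nearest NRF1, a regulator of mitochondrial biogenesis, was higher, at 1.22 in the authors' first deposited table. Its mean level was 55.7 normalised reads, against 142 at the median peak of that table. The NRF1 promoter stood at -0.71 and -0.80 in the authors' deposited tables.

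Cell cycle and replication genes had medians of -1.07 (percentile 5.16) and -1.34 (percentile 11.6), both inside the random range. With the trends by level and by chromosome region removed, the percentiles were 32.4 and 17.7. A peak lower by at least 1 was present at 20 of 29 of these genes in the first table (percentile 99.1 of lists matched on peaks per gene) and at 27 of 28 in the second (percentile 96.8). In the authors' deposited tables the promoters of TOP2A, a DNA topoisomerase, stood at -1.21 and -1.96 and of CDC6, a replication licensing factor, at -1.06 and -1.88. RRM2, a ribonucleotide reductase subunit, had a promoter peak starting at 10122311 of chromosome 2 with -1.84 and, at the overlapping peak, -1.47, and another starting at 10120112 with -1.16 and -1.88 in the authors' deposited tables. All 3 genes lie in the shifted chromosome segments described below. The list of H4K20 methylation and chromatin condensation, which holds KMT5A, had medians of -1.04 (percentile 19.9) and -1.40 (percentile 4.82). CDC20, a mitotic activator, had -1.38 and -1.63, and SMC2, a condensin subunit, -1.42 and -1.42 in the authors' deposited tables. Targets of p53 had medians of -0.975 (percentile 38.4) and -1.22 (percentile 74.7), with MDM2 at -1.38 and -1.50 in the authors' deposited tables. AP-1 and immediate early genes stood at percentiles 53.6 and 53.2, with an intronic FOSL2 peak at -1.81 and -1.70 in the authors' deposited tables.

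Interferon response genes were low in the first table only, by the random-list range. Their median there was -1.20, at percentile 0.99, against -1.33 in the second, at percentile 27.2, and the difference between the tables was not tested. The promoters of IRF9, a transcription factor of interferon signalling, and of ISG20, an interferon-stimulated gene, had -1.76 and -1.34 in the authors' first deposited table and -0.92 and -1.51 in the authors' second deposited table, where IRF9 was 0.31 above the median. Markers of other cell types were few. Erythroid and megakaryocyte markers had medians of -1.31 (percentile 4.29) and -1.55 (percentile 5.64), and with the trends by level and by chromosome region removed the percentiles were 0.24, outside the random range, and 22.2, over 5 and 3 genes. Among them were TFRC, the transferrin receptor, at -1.84 and -1.55 and ITGA2B, a platelet integrin, at -1.31 and -1.69 in the authors' deposited tables. Lymphoid markers stood at percentile 89.9 in the first table and had 2 genes with a promoter peak in the second, too few for a percentile. A weak distal peak nearest CD5, a T cell marker, with a mean level of 54.2 normalised reads, was at 1.00 in the authors' first deposited table. Non-haematopoietic markers had 3 promoter peaks in the first table, with a median of -0.93 (percentile 47.8), and 0 in the second. No list lay outside the central 95% of random lists in both tables. By medians as deposited, 3 did so in the first and 0 in the second. With the level trend alone removed, 2 did so in the first, oxidative phosphorylation and interferon response, and 1, the LSC17 genes, in the second. With both trends removed 2 did so in the first, interferon response at percentile 0.315 and the erythroid and megakaryocyte markers, and 0 in the second. By the share of genes with any peak lower by at least 1, 1 did so in the first and 0 in the second. Counting promoter peaks only, 1 did so in the first, oxidative phosphorylation, and 2 in the second, the LSC17 genes and myeloid differentiation (percentiles 0.095 and 1.94). Counting peaks within 50 kb, 3 did so in the first, oxidative phosphorylation, mitochondrial apoptosis and the cell cycle genes, and 0 in the second. These counts are not corrected for the number of lists and measures, so some lists can lie outside by chance.

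**Figure D2:**
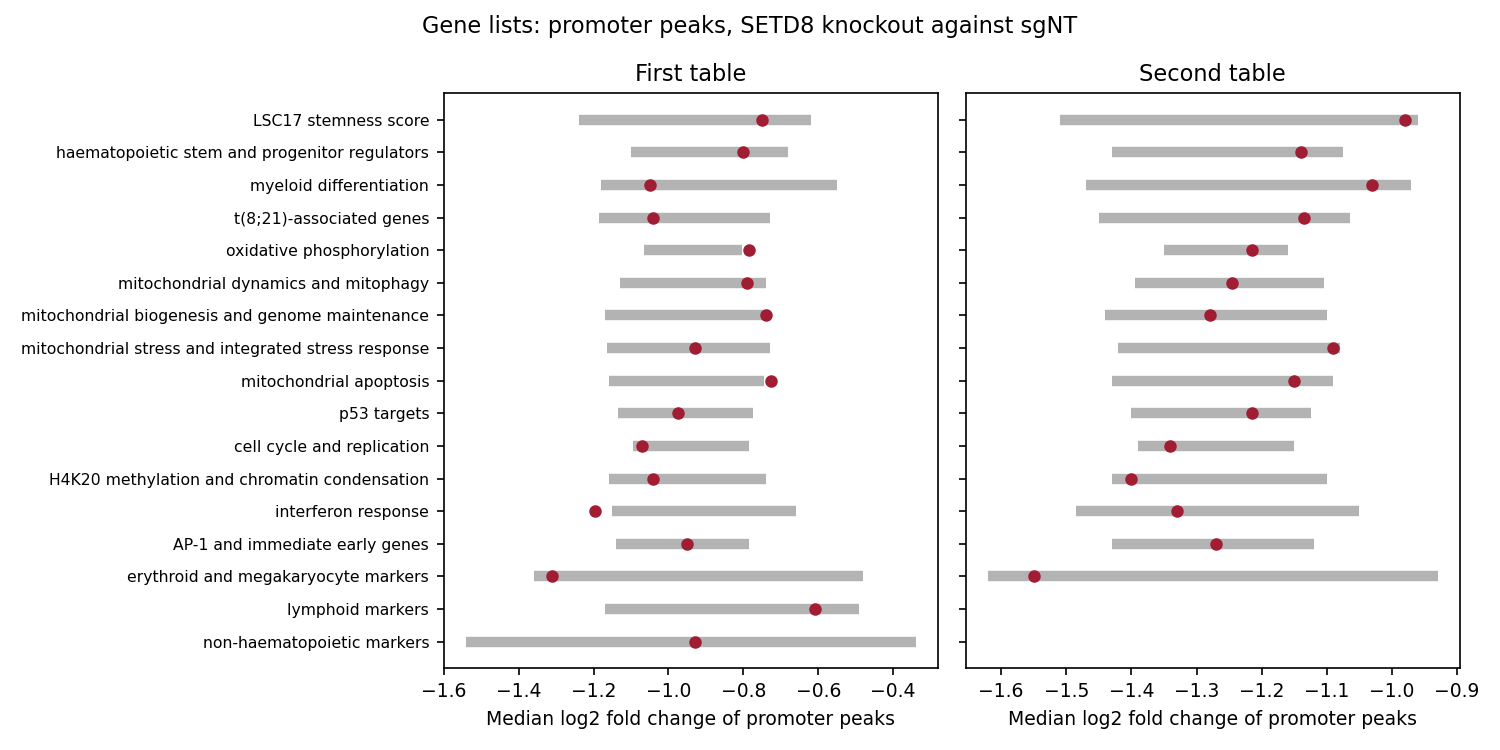
Median log2 fold change of the promoter peaks of each gene list (red points, horizontal axis, a separate scale per panel) and the central 95% of 10000 random lists matched on peak level (grey bars), for each table. Oxidative phosphorylation and mitochondrial apoptosis lie above the bar and interferon response below it in the first table, and no list lies outside its bar in the second, where 2 lists with too few genes have no point.

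The tables shared 11117 peaks, and peak levels correlated between them across peaks (r = 0.825). The fold changes did so weakly, with Pearson r = 0.229 and Spearman rho = 0.197 across peaks, which are not independent replicates. Nearly all joined peaks (98.1%) had the same sign, while 56.3% lay on the same side of both medians. The correlation was 0.206 at promoters and 0.290 at other sites. With the trends by level and by 5 Mb region removed, it was 0.0794.

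Large chromosome segments went together. Peaks of chromosome 17 between 26.88 and 83.12 Mb, of chromosome 2 between 6.917 and 89.84 Mb and of chromosome 9 between 75.03 and 134.4 Mb were lower than the rest of their chromosomes, and those of chromosome 8 between 85.11 and 145 Mb were higher, in both tables. The chromosome 17 segment holds TOP2A, CDC6, ATP5PD, ATP5MC1, PHB1, JUP and ITGA2B, the chromosome 2 segment MTHFD2, RRM2 and FOSL2, the chromosome 9 segment PSAT1 and SMC2, and the chromosome 8 segment MYC and COX6C, besides the ranked peaks marked above. Median fold changes inside and outside the segment were -1.09 and -0.71 for chromosome 17 in the first table and -1.58 and -1.25 in the second. They were -1.25 and -0.94, then -1.54 and -1.25, for chromosome 2, and -1.28 and -1.04, then -1.55 and -1.27, for chromosome 9. For chromosome 8 they were -0.62 and -0.83, then -0.91 and -1.11. By whole chromosomes, 9 of 23 stood off the table median in the same direction in both tables, with bootstrap intervals that exclude it. Chromosomes 2, 9, 17 and X were lower and chromosomes 8, 18, 19, 21 and 22 higher. Among peaks at or above the median level 7 did so, without X and 19, and among peaks other than promoters 6, without X, 18 and 21. The segments were delimited in the second table and then read out in the first. Across 425 bins of 5 Mb the level-adjusted medians of the tables correlated with r = 0.586 and rho = 0.475, where the highest of 415 rotations of the bins gave 0.212.

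**Figure D3:**
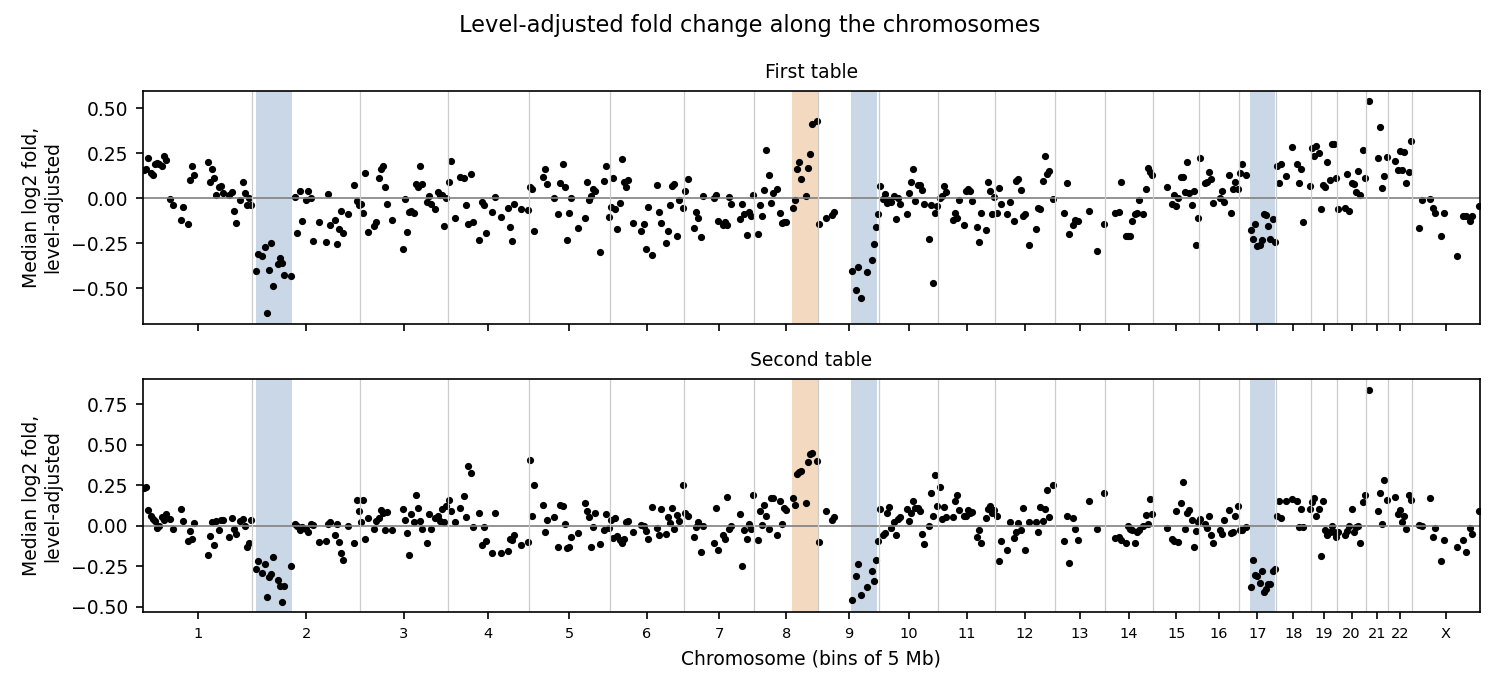
Level-adjusted median log2 fold change of peaks in bins of 5 Mb (points, vertical axis) along the chromosomes (horizontal axis) for each table; blue shading marks the segments that were lower and orange the one that was higher. The points of the shaded segments of chromosomes 2, 9 and 17 lie mostly below 0 and those of chromosome 8 mostly above 0 in both tables.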

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

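The rescaling to reads in peaks, the level-bin and 5 Mb adjustments, the set outside the segments, the autosomal medians and the centred block were chosen after the data were seen. No peak passed an adjusted p of 0.05 or 0.01 in either table, with or without the weaker peaks. At a fold size of 0.58, 14859 peaks were lower and 350 higher in the first table and 43 higher in the second. Centring left 408 lower and 1134 higher by at least 1 in the first table and 28 and 277 in the second. Rescaling, in effect the same step there, gave the same 28 and 277. Among peaks at or above the median level there were 4885 and 5 in the first table and 5864 and 0 in the second. The median fold change over all peaks was then -0.97 and -1.27, and 0.000311 after rescaling of the second table. The first-table difference of promoter minus other peaks turned to 0.05 at or above the median level, 0.035 after the level adjustment and 0.0225 after both. In the second table these gave 0.09, 0.09 and 0.10. The cause of the turn was not tested beyond the level trend. Centring put the KMT5A promoter at 0.05 in the first table and -0.22 in the second. The promoter share of peaks lower by at least 1, 61.9% and 82.0%, was 57.3% and 79.0% with promoters within 1 kb, and 77.2% and 92.3% at or above the median level. The correlation between tables was 0.207 at or above the median level, 0.195 and 0.0794 after the level and both adjustments, and 0.152 outside the segments. Treating the numbers as pairs, a replicate block over the 2 fold changes of each joined peak gave 10542 peaks by limma as deposited, 10540 lower and 2 higher, and 18 once centred, 15 lower and 3 higher, against 0 by the authors' test. At an unadjusted p under 0.05 the centred fit had 887 lower and 353 higher, with no chance count computed for this fit. Whether the numbers pair samples could not be checked. The fit also takes the 2 fold changes as independent, while the libraries of the first table are not named. As deposited, its count restates the shift shared by nearly all peaks. The other 25 settings kept their direction, with counts within 1.5 times, though chromosomes off the median in both tables went from 9 to 7 at or above the median level and to 6 without promoters. Leaving out a replicate was not run because the second table has 1 library per group and those of the first are not mapped to samples. The count-test, scaling-factor, count-filter, pseudocount and motif alternatives were not run, for want of counts for all libraries and of a genome. Depth limits single peaks, as counting error spans 0.298 at the median.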

Other observations

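The tests of the global shift, of peak levels between chromosomes, of libraries shared between tables and of vector reads below were chosen after the results were seen, as were the peaks shared between tables. Some sites were lowered less than most in both tables. With a size of 0.58 from each table's median, 89 joined peaks were on the retained side in both, where independent tables would give 20.02, and with the level trend removed 58 were, against 19.5. Fold changes spread more among weak peaks, with standard deviations of 0.67 and 0.636 in the lowest level decile against 0.307 and 0.251 in the highest. Weak peaks can thus pass 0.58 in both tables by noise, and removing the level trend leaves this spread. Libraries shared between the tables would also raise the overlap, so the excess over these numbers need not mean shared sites. KMT5B, which encodes an enzyme that adds further methyl groups to H4K20, had such a promoter peak on chromosome 11 at 68213585 to 68214154, with fold changes of 0.35 and -0.28 in the authors' deposited tables, 1.22 and 0.95 above the medians. That peak was weak, with mean log2 levels of 5.94 and 6.99 against table medians of 7.15 and 7.72. Other peaks on the retained side were promoters of IL10RA, an interleukin receptor gene, at 0.42 and -0.42, and of SNX9 at 0.43 and -0.46, an intron annotated to ERCC1, a DNA repair gene, at 0.97 and -0.35, and a site near GADD45B at 0.03 and -0.46 in the authors' deposited tables. Farthest above both medians were peaks near TEKT4P2 and MIR6724-1 on the short arm of chromosome 21, at 1.08 and 0.90 and at 2.18 and 0.45 in the authors' deposited tables. Their mean log2 levels, 6.17 and 7.53 and then 6.89 and 7.42, lay below the table medians, and how uniquely reads map there was not analysed here.

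The same limit of uneven spread holds on the lower side. There 110 joined peaks were shared, where independent tables would give 45.8, and 76 of them (69.1%) lay in the shifted segments. They include, inside the segments, the promoters of ABL1, a tyrosine kinase, at -1.66 and -2.21, and PTCH1, the Hedgehog receptor, at -1.67 and -2.01 in the authors' deposited tables. The ROBO1 promoter, at -1.81 and -1.92 in the authors' deposited tables, lies outside them.

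Nearly all peaks were lower in the knockout. Fewer reads in peaks in the knockout library would give this, but the ratio of unscaled reads in peaks of the second table, 0.391 with a control scaling factor of 0.918, restates the fold changes and cannot decide it. One scaling factor that is off would move weak and strong peaks alike, yet the lowest and highest deciles by level differed by at least 0.39 in both tables. Since weak peaks called in only 1 library can show the same trend, a wrong scaling factor cannot be told apart from a real shift by this value. A smaller library, a lower share of reads in peaks, and lower accessibility after loss of SETD8 all stay open and untested, since total library sizes were not analysed here.

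The chromosome segments may reflect copy number that differs between the compared cells. All 8 pairs of segment and peak class in the first table, promoters and others alike, were shifted in the direction seen in the second table, with intervals that exclude 0. A mere difference in peak level between chromosomes is argued against by the correlation of 0.586 between the tables after level adjustment. First-table fold changes rose by 0.265 (0.202 to 0.323) per unit of second-table ones over 1895 peaks with a reciprocal overlap of at least 90%. The replicate 2 pair as an equal part of the first table would give 0.5 or more, if its fold changes were measured alike in both. Counting error in the second table pulls this slope down, so the same libraries in both tables cannot be excluded by it. An effect of the knockout on whole segments was not tested and stays open.

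The EEF1A1 promoter peak and a peak annotated to RNU6-9, a U6 small RNA gene, on chromosome 15 at 67839957 to 67840455 were the strongest of the second table, with mean log2 levels of 15.09 and 11.04, against 9.77 and 7 in the first, where they ranked 477 and 11057. Reads of an integrated vector with EF1-alpha and U6 promoters could give this, and no source used here names the vector. The peaks had the largest level gains between tables, 5.32 and 4.04, at ranks 1 and 2 of the joined peaks, though the EEF1A1 peaks overlap by only 392 of 1316 bp, while the first-table RNU6-9 peak spans all 499 bp of the other. A general gain of strong promoters is argued against, as the 100 strongest promoters had a median gain of -0.735 when chosen on the first table, which pulls the gain down, and of -0.345 when chosen on the second, which pulls it up, against -0.02 over all joined peaks. The EEF1A1 peak held 35610 knockout and 34160 normalised control reads, so the explanation would bear on both libraries, and their folds of 0.07 and -0.34 in the authors' second deposited table would then not measure these genes.

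The 10 strongest peaks of the first table held 64.7% of its summed mean level, had fold changes between -0.79 and -0.25 in the authors' first deposited table, and joined 0 peaks of the second. They lie at 629115 to 634886 on chromosome 1, near PCBD2 on chromosome 5, and at LINC00399, EPHA6 and MTRNR2L8, a nuclear copy of mitochondrial sequence. Whether mitochondrial reads make up these peaks was not tested. The 10 strongest of the second table held 1.42%.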
